A study of Mus musculus with 18 samples.

How the data were processed

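The series holds 18 samples, 9 for gene expression and 9 for the T cell receptor (TCR), from 8 mice. Per the labels' protocols, live T cells were sorted from tumors of FVB/NJ rtTA-HER2d16 mice, with 3000 cells targeted per sample, and taken through 10x Genomics libraries that read transcripts from their 5′ ends, together with TCR chains. Tumors 403A and 403B came in 1 deposited matrix without a map from barcodes to tumors, so that there are 8 gene expression libraries. The mm10 build, Cell Ranger 2.1.0 and Seurat 3.1.2 are named in the submitters' processing notes without a role, and the annotation release and the cell filter are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, and the deposited clonotype tables, per the file headers, hold the number of cells (a count) per clonotype with its CDR3 sequences. Clonotype tables carry no barcodes, so that receptors could not be joined to cell classes. The lowest UMI count of a barcode lay near the minimum of 500 used here, so barcodes had been filtered to some extent before deposit.

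Of 31053 gene identifiers, 30934 matched the GENCODE vM21 annotation (GRCm38, the mm10 build), from which positions were taken, and 28 symbols were shared by more than 1 identifier. Total UMIs per library were 14178695, 7346658 and 22712858 in isotype 1, 2 and 3, 57047925 and 15157300 in anti-PD1 1 and 2, 8833834 in vaccine 1, and 16393743 and 12233131 in combination 1 and 2. Barcodes with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, 17024 of 19401. Scrublet (in scanpy 1.11.5) marked 24 of them (0.141%) as doublets and these were removed. A caller that marks so few has not worked, and in an alternative the 390 highest scores were removed, at 0.8% per 1000 barcodes.

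Counts per cell were scaled to 10000 and log-transformed, and 2000 variable genes were taken without receptor and immunoglobulin segments, mitochondrial and ribosomal protein genes and the proliferation, interferon and immediate early lists. After scaling (values limited to 10), 30 principal components, 15 neighbors and Leiden clustering at resolution 1 gave the clusters (igraph 0.11.9, scikit-learn 1.9.0, seed 0), first over all cells and then over T cells. The plan had been 1 clustering of all cells, with genes scaled within each library. It split cell types by library. Scaling over all libraries and the second clustering of T cells alone replaced it after the library makeup was seen and before any test. The planned clustering was kept as an alternative, which thus differs in both the scaling and the number of steps. Clusters were named from marker lists fixed before the data were examined, as were the gene lists, the tests and most alternatives, while the naming of each cluster followed its leading genes. Clusters 3, 5, 6, 14, 16 and 17 of the T cells stayed without a name and out of every class, but counted in the total of T cells. Cluster 3 (Gzma, Gzmb, Gzmc and Cd7 lead) held 20.1%, 14.2% and 2.88% of T cells in isotype 1, 2 and 3, 0.87% and 1.54% in anti-PD1 1 and 2, 0.71% in vaccine 1, and 0.17% and 0.12% in combination 1 and 2. Cluster 6 (Gm26917, Csn3, Csn2 and H2-Aa lead), with few UMIs per cell, held 35.3% of T cells in vaccine 1, 8.03% in combination 2 and 3.59% or less elsewhere. Cluster 5 (Apoe, Csn2 and Lyz2 lead) held 6.19% in vaccine 1, 5.23% in anti-PD1 1 and 1.66% or less elsewhere. Cluster 14 (Izumo1r, Gpr83 and Foxp3 lead) held 0.58%, 1.10% and 3.07% in isotype, 0.22% and 5.27% in anti-PD1, 0.07% in vaccine 1, and 0.33% and 2.91% in combination. Cluster 16 (Gm26917 and Lncpint lead) held 4.75% in combination 2 and 0.57% or less elsewhere. Cluster 17 (Ighv3-8, Igkv1-110 and Igkv15-103 lead) held 1.80% in combination 2 and 0.03% or less elsewhere. The cycling cluster was likewise no class of its own in the gene tests.

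UMI counts were summed per library and class, with at least 20 cells in each. CD8-like sums held 115, 169 and 289 cells in isotype 1, 2 and 3, 117 and 137 in anti-PD1 1 and 2, 525 in vaccine 1, and 494 and 319 in combination 1 and 2. CD4-like sums held from 46 cells (anti-PD1 1) to 458 (combination 1), and Treg-like sums from 50 (combination 2) to 183 (anti-PD1 1). The main test was edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, 4 treatment groups in 1 fit, Benjamini-Hochberg adjusted p threshold of 0.05, R 4.3.3). The standard error is the log2 fold change divided by the square root of F. DESeq2 1.42.0 was an alternative. Gene lists (28) were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry (limma 3.58.1), adjusted over lists and comparisons of a class. Levels are CPM, counts relative to the library size of the class. On data simulated from these libraries (8905 genes, CD8-like cells, combination against isotype) the test recovered 10% of genes changed by a factor of 2 and 71% of those changed by a factor of 4, and 11 of 92 calls (12.0%) were unchanged genes. That last share lies above the threshold of 0.05, in 1 simulation. Simulated genes varied independently, with no series effect and no difference in cluster makeup, so these rates may not hold for the real libraries.

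The cycling share was taken over CD8-like cells together with those cells of the cycling cluster that had a Cd8a or Cd8b1 UMI and no Cd4 or Foxp3 UMI. Cells were called cycling with at least 2 UMIs over 6 genes (Mki67, Top2a, Birc5, Ube2c, Cdk1 and Ccnb2), with a second value after thinning cells to 1500 UMIs, which leaves out cells with fewer. Shares, ratios and receptor measures were compared by exact two-sided permutation tests over libraries or mice, 21 in the family, with Benjamini-Hochberg adjustment (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). The smallest p these can give is 0.0179 for 3 against 5, 0.0286 for 4 against 4 and 0.1 for 2 against 3. Clonality is 1 minus the normalized Shannon entropy of clonotype sizes, averaged over 1000 draws of 405 cells, and a clonotype of at least 2 cells counts as expanded. For the mouse with 2 tumors the measures were computed per tumor and averaged, and it counts as 1 mouse. Intervals of clonotype shares are 95% Wilson intervals and cover counting error only.

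The genes named were set by a rule: those past the threshold whose libraries do not overlap between the groups, largest changes first, plus a fixed panel of 25 genes and the leading members of lists that passed. Receptor variable, diversity and joining segments, predicted models, and mitochondrial and ribosomal protein genes were left out of the first part. Within the panel and the lists, a narrower choice by smallest p (6 panel genes in each of 4 main comparisons and 3 in the others, Pdcd1 always, and 2 members of each of 4 lists) was made after values were seen. It replaced a first choice by hand that had partly left out genes whose sign changed between alternatives, which would have made results look steadier. The labels do not say that the numbers of the mice mark batches, but mice numbered 401 to 471 and 663 to 672 were compared within each series and a term for the series was tried. Other alternatives were another normalization, no filter on low counts, other cell classes and clusterings, other treatment of doublets, other clonotype definitions, and leaving out each library in turn. Replicate numbers follow the order of deposit only and pair no libraries. Figures were drawn with matplotlib 3.10.9.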

Results

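Tumor-infiltrating T cells were profiled from HER2-driven mouse breast tumors after 4 treatments. The mice were FVB/NJ animals of the rtTA-HER2d16 model, in which a form of the HER2 oncogene is switched on in the mammary gland and tumors then arise on their own. Mice received an isotype control antibody, an antibody against the inhibitory receptor PD-1 (anti-PD1), an adenoviral vaccine carrying HER2d16 (vaccine), or vaccine and anti-PD1 together (combination), given weekly from the time a tumor could be felt. Live T cells were sorted and taken through droplet-based sequencing of transcript ends and of T cell receptor (TCR) chains. The gene expression data came as 8 matrices from 8 mice, with 3 isotype, 2 anti-PD1, 1 vaccine and 2 combination libraries. Anti-PD1 1 pooled 2 tumors of 1 mouse in 1 matrix, so it counts as 1 library. The matrices held 19401 barcodes, from 998 in isotype 2 to 3979 in anti-PD1 1, and 17000 passed the cell filters. Total counts ran from 7346658 UMIs in isotype 2 to 57047925 in anti-PD1 1, and the median per barcode from 2307 in vaccine 1 to 12874 in anti-PD1 1. Each library comes from a different mouse, and the single vaccine library was assumed in the gene tests to vary like the others.

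The T cell makeup differed widely between libraries, also between those of 1 treatment. Naive-like T cells, with Lef1 and Dapl1 among their leading genes, made up 69.8% of T cells in isotype 3, 73.5% in anti-PD1 2 and 61.1% in combination 2. In the other libraries they made up between 0.58% (combination 1) and 11.3% (isotype 1). CD8-like cells made up 41.0% of T cells in combination 1, 37.4% in vaccine 1, 25.5% in anti-PD1 1, 23.3% in isotype 2, 13.3% in isotype 1, 13.1% in combination 2, 9.55% in isotype 3 and 5.87% in anti-PD1 2. The naive-like clusters lie outside this class. A transcript gate (Cd8a or Cd8b1 and no Cd4 or Foxp3 UMI) over all T cells gave other numbers. CD8-like cells were then 1028 against 289 in isotype 3, 740 against 137 in anti-PD1 2 and 828 against 319 in combination 2. They were also more in vaccine 1 (855 against 525) and anti-PD1 1 (140 against 117). In combination 1, isotype 1 and isotype 2 they were fewer. CD4-like cells that were not regulatory were most frequent in combination 1 (38.0%), isotype 2 (21.5%) and isotype 1 (18.3%). Regulatory (Treg-like) cells, which carried Foxp3, Il2ra and Tnfrsf4, made up 39.9% of T cells in anti-PD1 1, 22.1% in isotype 2 and 20.1% in isotype 1, against 10.9% or less elsewhere. Th17-like cells with Il17a and Il17f reached 5.56% in isotype 1 and 5.45% in anti-PD1 1. Although T cells had been sorted, only 13.5% of the kept cells of anti-PD1 1 were T cells and 66.8% were Myeloid-like, while T cells made up 72.4% to 97.0% of the other libraries.

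**Figure D1:**
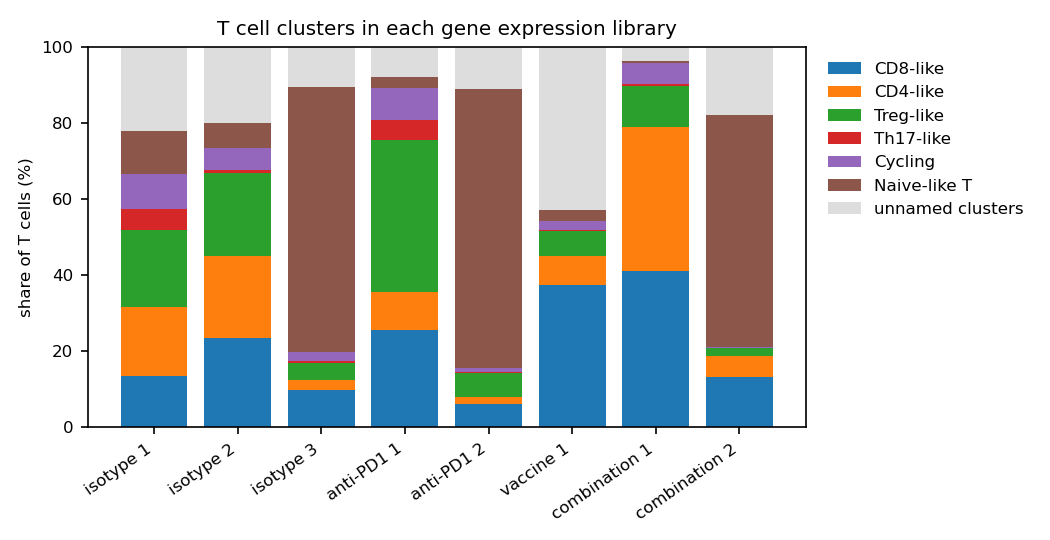
Stacked bars give the share of T cells (in percent) in each named cluster class for the 8 gene expression libraries, with clusters that stayed unnamed in grey. The naive-like share lies at 61.1% or above in isotype 3, anti-PD1 2 and combination 2, and at 11.3% or below in the others.

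The first comparison asked whether giving vaccine shifted the balance of regulatory and CD8 T cells. The 3 vaccinated libraries held fewer Treg-like cells per CD8-like cell than each of the 5 libraries without vaccine. The ratio was 0.181 in vaccine 1, 0.265 in combination 1 and 0.157 in combination 2. Without vaccine it was 1.51, 0.947 and 0.471 in isotype 1, 2 and 3, and 1.56 and 1.07 in anti-PD1 1 and 2. The means were 0.201 ± 0.057 (SD, n = 3) with vaccine and 1.11 ± 0.449 (SD, n = 5) without, with p = 0.0357 in an exact two-sided permutation test over 56 splits and an adjusted p of 0.5 over the family of 21 tests. The difference was thus not past the adjusted threshold. It was −1.08 among the mice numbered 401 to 471 and −0.603 among those numbered 663 to 672. The CD8-like share of T cells averaged 30.5% ± 15.2 (SD, n = 3) with vaccine and 15.5% ± 8.57 (SD, n = 5) without (exact permutation p = 0.125), and the Treg-like share 6.56% ± 4.41 against 18.6% ± 14.3 (exact permutation p = 0.268). The difference in the CD8-like share was 9.71 percentage points without combination 1, 23.7 without combination 2 and −9.60 with Leiden resolution 0.5, and that in the Treg-like share −6.69 without anti-PD1 1. Among T cells outside the naive-like clusters, a denominator chosen after seeing the data, CD8-like cells averaged 37.8% ± 3.87 with vaccine and 24% ± 6.09 without, and Treg-like cells 7.72% ± 2.90 and 25.2% ± 9.59 (SD, n = 3 and n = 5). In both measures all libraries with vaccine lay on 1 side of all others (exact permutation p = 0.0179 for each, the smallest possible, adjusted p = 0.375). With cluster 3 also counted as CD8-like, the CD8-like shares were 38.2% and 34.8% (exact permutation p = 0.446) and no longer lay apart. With class by transcript gate or with coarser clusters (Leiden resolution 0.5) the vaccinated libraries no longer lay below all others in the Treg-like to CD8-like ratio, with differences of −0.444 and −0.719. Cluster 14, which has Foxp3 among its leading genes, was left out of the Treg-like class. With it counted, an alternative chosen after seeing the data, the ratio was 0.183, 0.273 and 0.379 in vaccine 1, combination 1 and combination 2 and 0.792 to 1.97 without vaccine (exact permutation p = 0.0357).

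**Figure D2:**
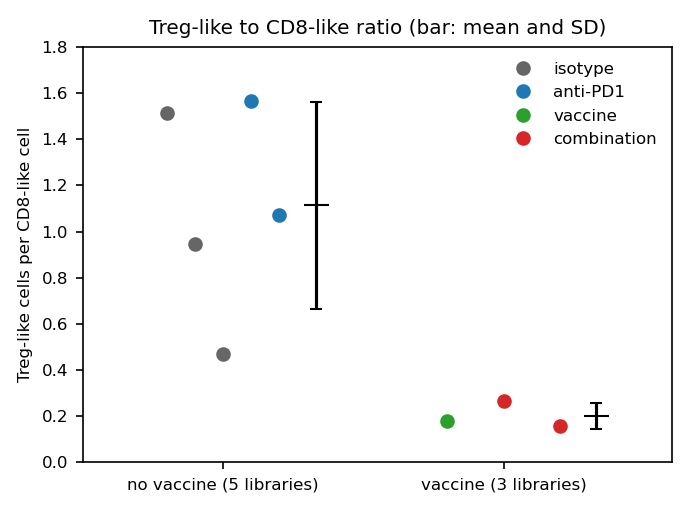
Points give Treg-like cells per CD8-like cell in each library, colored by treatment, and the bars give the mean and SD. The 3 libraries with vaccine lie between 0.157 and 0.265 and the 5 without between 0.471 and 1.56.

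Other cell shares differed less clearly between treatments. In combination against isotype, the Treg-like to CD8-like ratio averaged 0.211 ± 0.077 (SD, n = 2) against 0.977 ± 0.522 (SD, n = 3), and the share of CD8-like cells in cycle, read from 6 mitotic genes such as Mki67 and Top2a, 8.76% ± 3.66 against 17.9% ± 4.75. The difference in the ratio was −0.498 without isotype 1. Thinned to 1500 UMIs per cell, the cycling share was 2.98% ± 0.72 against 6.33% ± 4.31 (exact permutation p = 0.5). With 2 and 3 libraries an exact permutation test cannot go below p = 0.1, and the values were p = 0.2 and p = 0.1. The cycling share was 11.2% ± 5.01 (SD, n = 3) with vaccine and 18.6% ± 3.75 (SD, n = 5) without (exact permutation p = 0.0714), and 4.46% ± 2.60 and 7.28% ± 3.42 when thinned (exact permutation p = 0.25). Before thinning, the difference was −4.81 percentage points without combination 2. For anti-PD1 given or not, CD8-like cells made up 21.3% ± 15.4 and 20.9% ± 12.4 of T cells (SD, n = 4 each), and the Treg-like to CD8-like ratio was 0.765 ± 0.672 and 0.778 ± 0.583 (exact permutation p = 1 and 0.971). The lowest adjusted p among all 21 tests of shares and receptor measures was 0.5.

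Combination treatment was next compared with isotype in CD8-like cells. Egr1, an immediate early transcription factor induced by receptor signaling, rose by 2.1 ± 0.23 (log2 fold change ± SE), from 59.3 ± 0.94 to 255 ± 92.5 CPM (SD, n = 3 and n = 2). Cd5, a receptor that tunes TCR signaling, rose by 1.57 ± 0.18, and Cd27, a co-stimulatory receptor, by 1.39 ± 0.20. Klrc2, which encodes an activating natural killer receptor, rose by 2.27 ± 0.32. Among the genes that fell, Tcrg-C1, a gamma delta receptor constant segment, fell by 4.02 ± 0.48, Tnfsf8, the ligand of CD30, fell by 3.91 ± 0.43, and Cish, an inhibitor of cytokine signaling, fell by 1.71 ± 0.24. Tnfsf8 is on the marker list of CD4-like cells and is a leading gene of the CD4-like cluster 0. Whether CD4-like cells within the class bear on its fall was not tested. In all, 15 of 9207 genes passed (edgeR quasi-likelihood test, adjusted p = 0.0462 for each), 8 higher and 7 lower, 1 of them a receptor variable segment. Sphk2 (1.77 ± 0.25), Dnajb9 (1.35 ± 0.18) and Lfng (1.33 ± 0.18) also rose. The chemokine gene Ccl3 was at 2.94 ± 0.37, but it is among the leading genes that define cluster 2 and is not counted as a finding here. Ly6g5b (−2.84 ± 0.37), Arrdc4 (−2.55 ± 0.34) and Qpct (−1.67 ± 0.22) also fell. Ly6g5b is a leading gene of a T cell cluster of the first clustering that is led by Xcl1 and Cd160, which also lead cluster 8 below. Each of the 15 had all libraries of one group above all of the other, which by chance 2 of the 10 splits of 2 and 3 libraries give for a gene, 1 in each direction. The cluster makeup of the class differed between the groups. Cluster 8 held 91.0% of the CD8-like cells of isotype 3, 35.7% of isotype 1 and 23.1% of isotype 2, against 7.29% and 7.84% in combination 1 and 2. Its first leading gene is Fcer1g, a natural killer cell marker. Its 10 leading genes hold 1 CD8-like marker and 1 marker of another class, so they leave its name uncertain, although 8 CD8-like markers were detected. Tcrg-C1 lay between −4.60 and −3.62 over all 19 settings, among them the one with cluster 8 set aside. Cluster 2 held 53.9%, 62.1% and 1.38% in isotype 1, 2 and 3 and 53.0% and 66.8% in combination 1 and 2. The count fell to 0 with class by transcript gate, and to 0 without isotype 1, without isotype 2 or without combination 2. It was 3 without combination 1, 60 without isotype 3, 191 with DESeq2 and 279 with a term for the number series of the mice. With cluster 8 set aside, an alternative chosen after seeing the data, 17 genes were called, 7 of them among the 15. With the clustering first planned, with genes scaled within libraries, 5 were called and 0 of the 15 were among them. The count was 0 with the highest Scrublet scores removed and 0 with the myeloid-rich anti-PD1 library set aside.

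**Figure D3:**
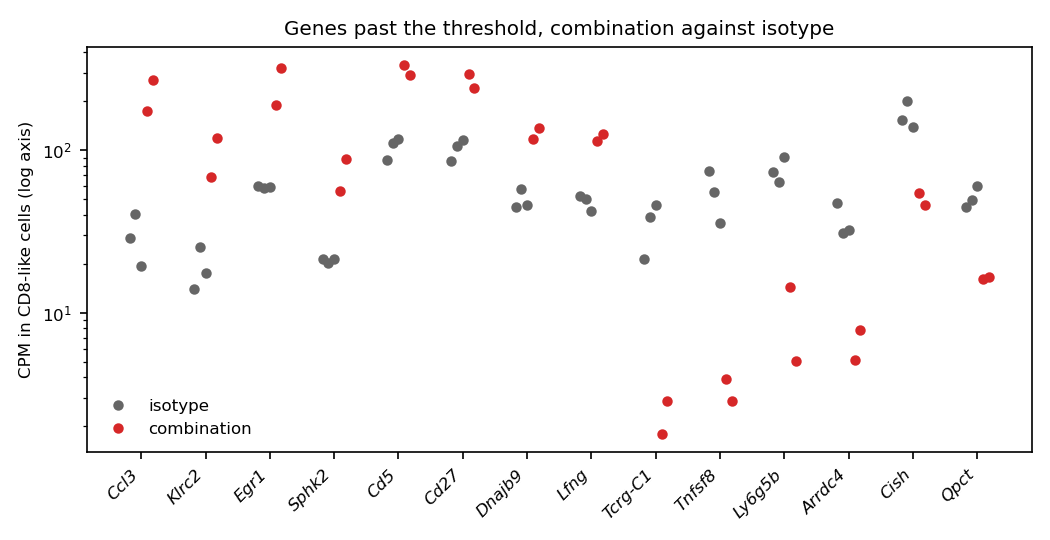
Points give CPM (log axis) in CD8-like cells of the 3 isotype and the 2 combination libraries for the 14 named genes past the threshold. For every gene the libraries of the 2 groups do not overlap.

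The named genes that passed lie on 11 chromosomes of the mm10 build. On it, Egr1 (ENSMUSG00000038418) spans positions 34859823 to 34864984 of chromosome 18, Cd5 (ENSMUSG00000024669) 10717116 to 10739002 of chromosome 19, Cd27 (ENSMUSG00000030336) 125232622 to 125237010 of chromosome 6 and Ccl3 (ENSMUSG00000000982) 83647844 to 83649355 of chromosome 11. Tcrg-C1 (ENSMUSG00000076749) spans 19214103 to 19217024 of chromosome 13, Tnfsf8 (ENSMUSG00000028362) 63831308 to 63861347 of chromosome 4 and Cish (ENSMUSG00000032578) 107296026 to 107302784 of chromosome 9. Tcrg-C1 is annotated as a receptor constant segment and the other 6 as protein-coding genes. Near-identical gamma constant segments can share reads, so Tcrg-C1 is uncertain against its family.

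Effector and residency genes of the fixed panel did not pass the test in CD8-like cells of the combination group. Itgae, the integrin chain that retains T cells in epithelia, was at −2.21 ± 0.39 (log2 fold change ± SE, adjusted p = 0.0594) and Ccr7, the lymph node homing receptor, at −1.91 ± 0.33 (0.0594). Like Ly6g5b, Itgae is a leading gene of the T cell cluster of the first clustering that is led by Xcl1 and Cd160. The cytokine gene Ifng was at 1.97 ± 0.51 (adjusted p = 0.107), the granzyme gene Gzma at −3.28 ± 0.94 (0.128), and the inhibitory receptor gene Tigit at 1.32 ± 0.40 (0.147). The exhaustion-linked factor gene Tox was at 1.40 ± 0.51 (adjusted p = 0.189). Pdcd1, which encodes PD-1, was at 0.71 ± 0.83 (0.677).

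Gene lists gave a broader picture of the same comparison, in camera with a preset correlation of 0.01. The inhibitory receptor and exhaustion list was higher, with a median log2 fold change of 1.16 over 17 members and an adjusted p of 0.00255, but adjusted p = 0.608 with an estimated correlation. No member passed over all genes, and 6 higher and 2 lower passed when adjusted over the list alone. Its members went both ways, with Nr4a2 at 1.92 and Cd160 at −2.99. Both are also leading genes of CD8-like clusters (Nr4a2 of cluster 2, Cd160 of cluster 8). The follicular helper list was higher, with a median of 1.11 over 6 members, led by Tox2 (4.58) and Sh2d1a (1.31), the 2 members that passed when adjusted over the list alone (adjusted p = 0.566 with an estimated correlation). Proliferation genes were lower, with a median of −0.45 over 23 members, among them Mcm3 (−0.88) and Mcm2 (−1.09) of the replication helicase, as were genes of the respiratory chain (−0.30 over 23, with Sdhd at −0.50 and Cox6c at −0.49) and of glycolysis (−0.23 over 13). These 3 calls are lost with an estimated correlation (adjusted p = 0.608, 0.608 and 0.582). When adjusted over the list alone in edgeR, 4 proliferation and 3 glycolysis genes were lower, and 0 respiratory chain genes passed. The cycling cluster lies outside the CD8-like class. The proliferation list thus covers only the cells left in the class, and not the proliferation of CD8 T cells as a whole. Gamma delta T cell markers were lower too, with a median of −2.21 over 6 members, with 5 of them lower when adjusted over the list alone, and immediate early genes, which tissue dissociation also induces and which include Egr1, were higher (0.42 over 18, 6 higher and 2 lower when adjusted over the list alone). Both calls are lost with an estimated correlation (adjusted p = 0.395 and 0.608). Whether the lower share of cluster 8 in combination bears on the gamma delta list was not tested. The cytotoxic list did not pass (adjusted p = 0.178), with a median of 0.62 and a mean of −0.28. Across the CD8-like comparisons 33 of 92 list tests passed. With an estimated correlation 0 passed, the lowest adjusted p being 0.395 with an estimated correlation, and fry passed 0.

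Anti-PD1 alone against isotype gave CD8-like cells with more interferon-stimulated transcripts as a list. The type I interferon list had a median log2 fold change of 0.95 over 20 measured members (camera adjusted p = 8.03e-17, but adjusted p = 0.566 with an estimated correlation). Isg15, a ubiquitin-like interferon-induced protein gene, was at 1.29 ± 0.29 and Ifi27l2a at 1.70 ± 0.45. When adjusted over the list alone, 2 members were higher. Isg15 is also a leading gene of cluster 8, which held 69.2% and 33.6% of the CD8-like cells of anti-PD1 1 and 2. It held 35.7%, 23.1% and 91.0% of those of isotype 1, 2 and 3, so the groups overlapped. In anti-PD1 1, Ifi27l2a reached 2147 CPM against 838 in anti-PD1 2 and 283 to 711 in isotype libraries. The naive and memory list was higher (median 0.36 over 14), with Slamf6 at 0.78 ± 0.30 and Ccr7 at 0.77 ± 0.30, and MHC class I genes were higher (median 0.14 over 13), with H2-T22 at 0.64 (adjusted p = 0.582 with an estimated correlation for both lists). Macrophage markers were also higher in these cells (median 0.94 over 10), and anti-PD1 1 was the library with 66.8% Myeloid-like cells. The tissue residency list was lower, with a median of −0.40 over 12. The macrophage and residency calls are lost too with an estimated correlation (adjusted p = 0.566 for both). Pdcd1 itself was at −0.11 ± 0.84 (log2 fold change ± SE). No gene passed in edgeR (0 of 9207, 281 at an unadjusted p under 0.05), and DESeq2 called 2.

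In CD8-like cells of vaccine 1, the only library with vaccine alone, the short-lived effector list was higher than in the 3 isotype libraries. The spread behind each p and SE comes from the other groups, so an effect of vaccine cannot be told from the makeup of this 1 mouse. The median was 0.68 over 12 members (camera adjusted p = 0.000745, 0.582 with an estimated correlation), with Klrg1, a marker of terminal effectors, at 2.19 ± 0.65 (12.3 CPM in vaccine 1 and 1.38 to 4.49 in isotype libraries). When adjusted over the list alone, no member of it passed in edgeR. The stem-like marker Slamf6 was at 1.28 ± 0.33 and Ccr7 at −1.51 ± 0.42 (log2 fold change ± SE). MHC class I genes were higher (median 0.36 over 13, H2-Q7 at 0.87), and respiratory chain genes were lower (median −0.23 over 23, Sdhd at −0.40), with adjusted p = 0.566 and 0.608 with an estimated correlation. Natural killer cell markers were lower, with a median of −2.96 over 7, and gamma delta markers −1.87 over 6 (adjusted p = 0.395 with an estimated correlation for both). Markers of mammary epithelium (median 3.17 over 6) and of macrophages (1.78 over 10) were higher in the same cells (adjusted p = 0.566 with an estimated correlation for both). Mammary epithelium genes made up 0.0340% of the UMIs of these cells, against 0.00791% or less in the CD8-like cells of the other libraries. Cluster 10 held 73.1% of the vaccine library's CD8-like cells and between 7.61% and 14.8% of those of the isotype libraries, with Gzmk, Ccl5 and S100a6 among its leading genes. Cluster 8, led by Fcer1g, Xcl1 and Cd160, held 4.76% of the CD8-like cells of vaccine 1 and 35.7%, 23.1% and 91.0% of those of isotype 1, 2 and 3. Whether this bears on the natural killer and gamma delta lists was not tested. In edgeR no gene passed (0 of 9207, 440 at an unadjusted p under 0.05), and DESeq2 called 18.

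Combination against anti-PD1 asked what the vaccine added to the antibody. In CD8-like cells the naive and memory list was lower in combination (median −0.66 over 14, camera adjusted p = 0.00049, 0.582 with an estimated correlation), with Ccr7 at −2.68 ± 0.36 and Id3, a regulator of memory precursors, at −2.44 ± 0.58. Proliferation genes were lower (median −0.57 over 23, Mcm2 at −1.30 ± 0.29), as were interferon-stimulated genes (−0.80 over 20, Bst2 at −1.33 ± 0.40), with adjusted p = 0.582 and 0.608 with an estimated correlation. Here too the proliferation list covers a class without the cycling cluster. The inhibitory receptor and exhaustion list was higher, with a median of 0.81 over 17 (adjusted p = 0.608 with an estimated correlation). Cluster 8, with Isg15 among its leading genes, held 69.2% and 33.6% of the CD8-like cells in anti-PD1 1 and 2 against 7.29% and 7.84% in combination 1 and 2. Itgae was at −2.03 ± 0.41 (log2 fold change ± SE) and the effector chemokine receptor gene Cx3cr1 at 1.94 ± 0.56, but at −1.55 with genes scaled within libraries. No gene passed in edgeR (0 of 9207, 1208 at an unadjusted p under 0.05), and DESeq2 called 55.

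Pooling the libraries by whether vaccine was given, Ccr7 was at −2.14 ± 0.33 (adjusted p = 0.107), Gzma at −3.53 ± 0.76 (0.172) and Itgae at −1.54 ± 0.34 (0.172) in CD8-like cells, as log2 fold change ± SE. In edgeR no gene passed (0 of 8667, 1137 at an unadjusted p under 0.05), DESeq2 called 99, and with the series term edgeR called 31. For anti-PD1 given or not, Ifng was at 0.89 ± 0.40 and Itgae at −0.56 ± 0.31, 0 of 8667 genes passed in edgeR (368 at an unadjusted p under 0.05), and DESeq2 called 2.

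In CD4-like cells, combination against isotype gave lower regulatory genes and lower glycolysis genes as lists. The regulatory list had a median log2 fold change of −1.29 over 14 measured members (camera adjusted p = 5.16e-05, 0.725 with an estimated correlation), with the chemokine receptor gene Ccr8 at −1.91 ± 0.38 and the transcription factor gene Ikzf4 at −1.93 ± 0.53. Ccr8 is also a leading gene of the Treg-like cluster, and whether Treg-like cells within the CD4-like class bear on its fall was not tested. Glycolysis genes had a median of −0.41 over 12, with Tpi1 at −1.40 ± 0.46 and Eno1 at −0.94 ± 0.36, and respiratory chain genes −0.26 over 23 (adjusted p = 0.725 and 0.694 with an estimated correlation). When adjusted over the list alone, 2 regulatory genes were lower, and 0 glycolysis and 0 respiratory chain genes passed. Interferon-stimulated genes were higher (median 0.30 over 16), with Ifit1 at 1.75 ± 0.55 and Isg15 at 0.76 ± 0.29 (adjusted p = 0.725 with an estimated correlation for the list). Cx3cr1 was at −2.40 ± 0.62 and Mki67 at −1.35 ± 0.58, in a class that leaves out the cycling cluster. Cluster 9 held 90.0% and 98.5% of the CD4-like cells of combination 1 and 2 and 100% of those of isotype 3, but 41.8% and 42.3% of those of isotype 1 and 2, the rest being cluster 0. No gene passed in edgeR (0 of 7158, 650 at an unadjusted p under 0.05), DESeq2 called 7, and with a term for the number series of the mice edgeR called 96.

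Anti-PD1 against isotype in CD4-like cells gave a higher T helper 2 list (median 1 over 5, camera adjusted p = 0.0352, 0.694 with an estimated correlation). Gata3, the lineage factor gene, was at 0.72 ± 0.28. Il1rl1, the IL-33 receptor gene, was at 2.42 ± 0.86, with 99.2 CPM in anti-PD1 1 and 13.6 in anti-PD1 2 (46 and 48 cells). Il1rl1 is also a leading gene of the Treg-like cluster, and Treg-like cells made up 39.9% of T cells in anti-PD1 1. No gene passed in edgeR (0 of 7158, 275 at an unadjusted p under 0.05) or in DESeq2 (0). In the vaccine library the regulatory list was lower than in isotype (median −1.38 over 14, camera adjusted p = 0.000133, 0.725 with an estimated correlation), with Ccr8 at −2.16 ± 0.53 and 2 members lower when adjusted over the list alone. Ccr8, like Il1rl1, is a leading gene of the Treg-like cluster. Cluster 9 held 91.4% of the CD4-like cells of vaccine 1 and 80.4% and 93.8% of those of anti-PD1 1 and 2, against 41.8%, 42.3% and 100% in isotype 1, 2 and 3. Ikzf4 was at 0 CPM in vaccine 1 and at 36.4, 34.2 and 15.1 CPM in isotype 1, 2 and 3. Glycolysis genes were lower too (median −0.46 over 12, Tpi1 at −1.75 ± 0.65), while mammary epithelium markers were higher (median 3.47 over 4), with adjusted p = 0.725 and 0.694 with an estimated correlation. In edgeR no gene passed (0 of 7158, 214 at an unadjusted p under 0.05) or in DESeq2 (0). Across the CD4-like comparisons 15 of 66 list tests passed, and 0 with an estimated correlation or with fry.

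In Treg-like cells, Klrg1, a marker of highly activated regulatory cells, was at −1.89 ± 0.24 (log2 fold change ± SE, adjusted p = 0.0958) in combination against isotype. Klrg1 is also a leading gene of the Treg-like cluster as a whole. It was at 83.2 and 96.6 CPM in the combination libraries and 255, 352 and 378 CPM in the isotype ones. The IL-7 receptor gene Il7r was at −0.92 ± 0.21 and the inhibitory receptor gene Lag3 at 0.89 ± 0.21 (adjusted p = 0.257 for both). No gene passed in edgeR (0 of 8520, 819 at an unadjusted p under 0.05), DESeq2 called 19, and with a term for the number series edgeR called 156. Anti-PD1 against isotype gave Klrg1 at −0.53 ± 0.21, Lag3 at 0.54 ± 0.21 and Pdcd1 at 0.16 ± 0.22. In edgeR no gene passed (0 of 8520, 175 at an unadjusted p under 0.05) or in DESeq2 (0), and 14 were called with the series term.

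The receptor data asked whether treatment changed clonal expansion. Clonality, from 0 for all clonotypes at equal size to 1 for a single clonotype, was computed after thinning each sample to 405 cells, with anti-PD1 1 given as the mean of its 2 tumors. It was highest in isotype 1 (0.0717), vaccine 1 (0.0691) and isotype 2 (0.0652), followed by combination 1 (0.0380) and combination 2 (0.0150). With only clonotypes that have an alpha and a beta chain, vaccine 1 was at 0.0443, near combination 1 (0.0410) and below isotype 2 (0.0701). It was lowest in anti-PD1 1 (0.00859), anti-PD1 2 (0.00389) and isotype 3 (0.00284). The low values of isotype 3, anti-PD1 2 and combination 2 go with their naive-like shares of 69.8%, 73.5% and 61.1%, but anti-PD1 1 had a lower value than combination 2 with 2.83% naive-like T cells. That share rests on 459 T cells of its gene expression library, while its tumors gave 604 and 405 cells with a receptor. The naive-like share of many of those receptor cells is thus not known. In the other mice the numbers lay closer, with 864 and 892 in isotype 1 and 2442 and 2346 in combination 2. Clonality averaged 0.0164 ± 0.0151 with anti-PD1 and 0.0522 ± 0.0330 without (SD, n = 4 each, exact permutation p = 0.143, adjusted p = 0.5), and 0.0407 ± 0.0272 (n = 3) with vaccine and 0.0304 ± 0.0348 (n = 5) without (exact permutation p = 0.661). The difference by vaccine was −0.00393 without vaccine 1 and 0.0231 without combination 2. The difference by anti-PD1 was −0.0451 among the mice numbered 401 to 471 and −0.0265 among those numbered 663 to 672, and that by vaccine −0.0105 and 0.0387. The value of −0.0265 comes from vaccine 1 (0.0691) alone. In that series isotype 3 (0.00284) lay below both mice with anti-PD1, anti-PD1 2 (0.00389) and combination 2 (0.0150). The largest clonotype was that of vaccine 1, with 125 of 1318 cells (9.48%, 95% Wilson interval 8.02 to 11.2) and the alpha chain CDR3 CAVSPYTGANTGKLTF without a beta chain. In combination 2 the largest held 98 of 2346 cells (4.18%, 3.44 to 5.06), with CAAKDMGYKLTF and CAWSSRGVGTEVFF, and in isotype 1 it held 71 of 892 (7.96%, 6.36 to 9.92), with the beta CDR3 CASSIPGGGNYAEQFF. The largest in combination 1 held 43 of 1303 cells (3.30%), that of isotype 2 30 of 677 (4.43%), and those of isotype 3 and anti-PD1 2 held 29 and 30 cells (1.02% and 1.42%). In the anti-PD1 1 mouse the largest held 9 of 604 cells of one tumor and 5 of 405 of the other.

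**Figure D4:**
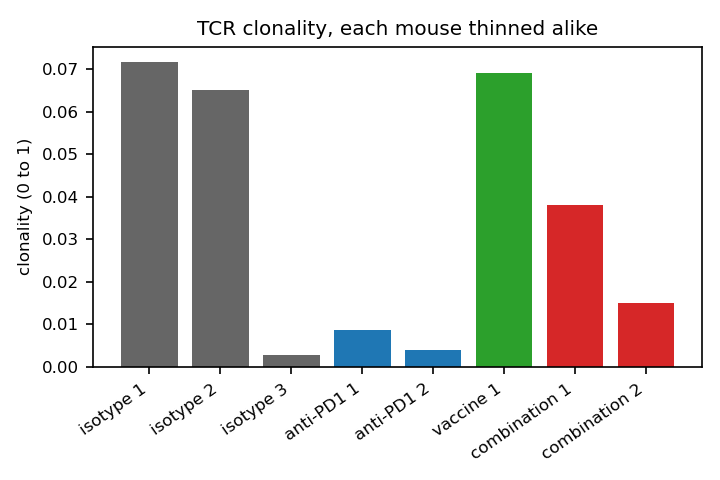
Bars give the TCR clonality of each mouse after thinning to the same number of cells, colored by treatment as isotype (grey), anti-PD1 (blue), vaccine (green) and combination (red). Isotype 1, isotype 2 and vaccine 1 lie at 0.0652 or above, and isotype 3 and anti-PD1 2 at 0.00389 or below.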

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

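The tests of naive-like cells and of cell ratios below were chosen after the results were seen. In 24 groups of 4 or 5 libraries the most distant value was compared with the others, and chance marks about 1 group in 20.

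Among the 4 libraries without anti-PD1, isotype 3 stood far from the others in 3 measures. Its cycling share of CD8-like cells was 23.4% against 15.1% to 16.2%, its TCR clonality 0.00284 against 0.0652 to 0.0717, and the share of cells in its 10 largest clonotypes 4.41% against 22.5% to 24.6%. The cycling share of isotype 3 depends on the setting: thinned to equal UMIs it was 11.3% against 3.28% to 7.40%, with genes scaled within libraries 17.4% against 14.04% to 17.9%, and with the transcript gate 9.53% against 13.9% to 15.2%. Among the 5 libraries without vaccine, T cells made up 13.5% of the kept cells in anti-PD1 1 against 72.4% to 92.7%.

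Cells other than T cells were found above the isotype level in some treated libraries. Myeloid-like cells made up 66.8% of anti-PD1 1 and 17% of combination 1 (3.73% to 11.6% in isotype). Epithelial-like cells made up 3.996% of anti-PD1 1 and 3.22% of vaccine 1 (0.889% to 2.26% in isotype) and Fibroblast-like cells 2.06% of anti-PD1 1 (0.178% to 0.754%). Genes of a salivary gland list, chosen after seeing the data, took 0.802% of all UMIs in combination 1, 0.544% in anti-PD1 2 and 0.0110% in vaccine 1, against 0.000150% to 0.0106% in isotype. Their source was not tested.

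Naive-like cells made up most T cells of isotype 3, anti-PD1 2 and combination 2, which are 3 of the 4 mice numbered 663 to 672 (the other being vaccine 1). Treatment as the whole cause is argued against by a range of 63.3 percentage points within isotype. The median UMIs of naive-like cells were 1.33 times those of other T cells in combination 2, 1.10 in anti-PD1 2 and 0.680 in isotype 3. Other T cells include the low-UMI clusters 6 and 16 (medians of 1097 and 1442.5), which held 196 and 116 T cells of combination 2. This lowers the median compared with, so shallow sequencing is not settled as the cause of the naive-like cells. Lymphoid tissue or blood carried along with the tumor may account for them, since B-like cells were found in the 3 libraries (26, 22 and 25 cells) and in none of the 5 others, with an exact permutation p of 0.0179 that takes all 8 libraries as exchangeable. Since all 3 come from 1 number series, a cause shared by that series stays open, and the explanation was found and tested on the same data.

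Fewer Treg-like per CD8-like cell were found with vaccine. The number series of the mice as the whole cause is argued against by a difference of −0.603 in the series with the smaller difference, and cells of cluster 3 left out of the class by a difference of −0.584 with that cluster included, the vaccinated libraries still lying below all others. Where class boundaries fall stays open, since the separation held under 1 of 3 alternatives for the classes set in advance (Leiden resolution 2) and not with the transcript gate or Leiden resolution 0.5. The separation also held with genes scaled within libraries, which was the clustering first planned. In alternatives chosen later it held too: the gate outside naive-like clusters and cluster 14 counted as Treg-like.

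Other splits of the libraries were tried for the counts of genes by treatment given or not. For vaccine given or not, edgeR called 0 genes in CD8-like cells (1137 at an unadjusted p under 0.05, 99 by DESeq2), and for anti-PD1 given or not 0 (368 at an unadjusted p under 0.05, 2 by DESeq2). With a count of 0 each split calls as many (56 of 56 and 35 of 35 splits), so these comparisons say nothing on chance. The highest other splits called 367 (isotype 3 with both anti-PD1 libraries) and 232 genes. The second followed the number series of the mice, and with a term for the series 31 genes were called for vaccine given or not and 0 for anti-PD1 given or not. Splits with so many genes point to a structure of the libraries, which was not tested further.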

How the results depend on the processing

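The alternatives that set libraries or clusters aside, count cluster 3 as CD8-like or cluster 14 as Treg-like, gate outside naive-like clusters count shares outside the naive-like clusters or remove the highest Scrublet scores were chosen after seeing the data. Scaling genes within libraries was the clustering first planned, and became an alternative when another replaced it. Under all alternatives, the 14 named genes past the threshold kept their direction in 252 of 252 values, 129 of them past the threshold. These genes, Ccl3 among them, had been chosen because their libraries do not overlap between the groups. Their direction could thus hardly reverse where the classes stayed the same, and the 252 values cannot be set against those of other genes. Of 1597 values of 99 other named gene results, 1394 kept direction and side of the threshold, 156 moved past it and 47 reversed, in 22 results. Of 324 values of 21 share and receptor results, 283 kept direction and side and 41 reversed, in 10 results. Where a cause is not named, the cause was not tested. The alternative with genes scaled within libraries is also a single clustering of all cells, so that it changes 2 choices at once. No paired analysis was possible because replicate numbers only follow the order of deposit.

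Counts of genes moved with the tool, the filter, a term for the number series, the cell classes and the libraries used. Setting the naive-rich libraries aside (isotype 3, anti-PD1 2 and combination 2) left 1 library each for anti-PD1, vaccine and combination. The spread in those fits came from isotype 1 and 2 alone. Their counts, given last below, cannot be compared with the other counts or read as an effect of treatment. DESeq2 called 191 genes in CD8-like cells for combination against isotype, 2 for anti-PD1 against isotype, 18 for vaccine against isotype, 55 for combination against anti-PD1, 99 for vaccine given or not and 2 for anti-PD1 given or not, and 7 in CD4-like and 19 in Treg-like cells for combination against isotype. Without a filter on low counts edgeR called 869, 76, 240, 472, 507 and 98 in the same CD8-like comparisons, 283, 67 and 133 in CD4-like cells for combination, anti-PD1 and vaccine against isotype, and 173 and 34 in Treg-like cells for combination and anti-PD1. With a term for the number series it called 279 and 1 in CD8-like cells for combination and anti-PD1 against isotype, 31 for vaccine given or not, 96, 3 and 1 in CD4-like cells and 156 and 14 in Treg-like cells. With the naive-rich libraries set aside it called 773, 313 and 750 in CD8-like cells for combination, anti-PD1 and vaccine against isotype, 759 for combination against anti-PD1, 322, 39 and 381 in CD4-like cells and 149 and 36 in Treg-like cells, in fits with fewer libraries.

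For combination against isotype in CD8-like cells, edgeR called 0 genes with class by transcript gate, 0 with the highest Scrublet scores removed and 0 with the myeloid-rich anti-PD1 library set aside, where the classes and libraries used gave 15 (1800 at an unadjusted p under 0.05, 191 by DESeq2). It called 146 with predicted doublets kept, 5 with genes scaled within libraries (0 of the 15 among them), 61 with the gate outside naive-like clusters (11 shared) 113 with cluster 3 counted as CD8-like (13 shared) and 17 with cluster 8 set aside (7 shared). For vaccine against isotype in CD8-like cells it called 2 with genes scaled within libraries, 3 with the gate outside naive-like clusters and 1 with cluster 8 set aside. In CD4-like cells, combination against isotype gave 1 with doublets kept and 273 with genes scaled within libraries. With genes scaled within libraries, combination 2 held 0 CD4-like cells and isotype 3 held 1, below the minimum for a sum. That CD4-like fit thus set combination 1 alone against isotype 1 and 2. Its count of genes cannot be compared with the other counts. The gate outside naive-like clusters gave 1 in Treg-like cells for combination and 6 in CD8-like cells for vaccine given or not. Gene lists passed 0 tests with an estimated correlation and 0 with fry in CD8-like and in CD4-like cells, by limma, and 25 of 75 with the gate in CD4-like cells. Leaving out each library in turn gave 0 to 60 genes for combination against isotype in CD8-like cells, 0 to 1 in Treg-like cells for combination and for anti-PD1, and 0 to 2 for vaccine given or not.

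Shares reversed as follows. With Leiden resolution 0.5 the CD8-like share differed by −9.60 for vaccine, −11.9 for anti-PD1 and −15.1 for combination against isotype, and Treg-like per CD8-like cell by 0.682 for anti-PD1. With genes scaled within libraries, the CD8-like share differed by −14.6 for anti-PD1 and −2.14 for combination, Treg-like per CD8-like cell by 4.73 and the cycling share by 1.15 for anti-PD1. With cluster 3 counted as CD8-like these were −8.35, −0.642 and 0.263 for the first 3. With cluster 3 counted and T cells outside the naive-like clusters as denominator, the CD8-like share differed by −6.97 for anti-PD1 and −2.05 for combination. For anti-PD1, the CD8-like share differed by −4.16 and the Treg-like share by −5.36 over all kept cells, the CD8-like share by −0.169 with the gate and −5.25 with the gate outside naive-like clusters. With the naive-rich libraries set aside, Treg-like per CD8-like cell differed by 0.0344 and the cycling share by 0.927 for anti-PD1, and the share in expanded clonotypes by −2.32 for vaccine. With cluster 14 counted as Treg-like, Treg-like per CD8-like cell differed by 0.168 for anti-PD1. Leaving out each library gave ranges that cross 0. For anti-PD1 they were −6.08 to 5.95 (CD8-like share), −6.96 to 5.64 (Treg-like share) and −0.280 to 0.232 (Treg-like per CD8-like cell). For combination they were −2.33 to 25.6 (CD8-like share) and −21.6 to 2.72 (expanded clonotypes). For vaccine they were −0.00393 to 0.0231 (clonality), −0.404 to 6.66 (10 largest clonotypes) and −2.63 to 9.29 (expanded clonotypes).

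Treg-like per CD8-like cell by vaccine stayed negative, at −0.444 with the gate, −0.719 with Leiden resolution 0.5, −1.36 with resolution 2, −1.10 with cluster 14 counted as Treg-like and −4.13 with genes scaled within libraries. The last value rests on anti-PD1 1, at 19.1 (497 Treg-like and 26 CD8-like cells), with the other 4 libraries without vaccine at 0.514 to 1.17.

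Named genes reversed in log2 fold change as follows. In CD8-like cells, Pdcd1 was at −0.0701 with genes scaled within libraries and −0.000659 with cluster 8 set aside for combination against isotype, and at −0.0389 with cluster 8 set aside for combination against anti-PD1, where Cx3cr1 was at −1.55 with genes scaled within libraries. For anti-PD1 against isotype, Cx3cr1 was at 2.61 with genes scaled within libraries, Gzmk at −1.89 and Tox2 at −0.37 with the naive-rich libraries set aside, and Klrg1 at −0.64 with the gate, −0.35 with genes scaled within libraries and −0.23 with the gate outside naive-like clusters. There Pdcd1 was at 0.16 with the series term, 0.30 with doublets kept and 0.0383 with cluster 8 set aside. For vaccine against isotype, Pdcd1 was at −0.53 with genes scaled within libraries, −0.64 with cluster 8 set aside, −0.52 with cluster 3 counted as CD8-like and −0.44 with the naive-rich libraries set aside. Pdcd1 was at −0.29 with cluster 8 set aside for vaccine given or not, and for anti-PD1 given or not at −0.67 with the gate, −0.22 with genes scaled within libraries, −0.0716 with cluster 3 counted as CD8-like and −0.78 with the naive-rich libraries set aside. In CD4-like cells for anti-PD1, Cx3cr1 was at 0.000539 with the gate outside naive-like clusters, Fasl at −0.46 and Klrg1 at 0.73 with the gate, and at −0.23 and 0.79 with the gate outside naive-like clusters. For vaccine, Cd69 was at −0.11 with doublets kept, Pdcd1 at 0.75 with the series term, and Tox2 at 0.85 with the gate and 0.14 with the gate outside naive-like clusters. In Treg-like cells, Pdcd1 was at 0.0183 with doublets kept for combination. For anti-PD1, Gzma was at 2.22 with the gate, 0.69 with genes scaled within libraries and 2.30 with the gate outside naive-like clusters, Lag3 at −0.12 and Pdcd1 at −0.39 with genes scaled within libraries, and Pdcd1 at −0.00309 with the naive-rich libraries set aside. Leaving out each library gave −1.72 to 2.59 for Gzmk and −1.34 to 0.55 for Pdcd1 in CD8-like cells for anti-PD1 against isotype, −0.44 to 0.49 for Pdcd1 for vaccine, −0.38 to 0.59 for Pdcd1 for anti-PD1 given or not, and −1.67 to 0.12 for Gzmb in CD4-like cells for anti-PD1.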

Other observations

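The tests of shared receptors below were chosen after the sequences were seen. Some beta chain CDR3 sequences were found in all 3 vaccinated mice and in none of the 5 others. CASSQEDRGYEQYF was found in 15 of 1261 cells with a beta chain in combination 1 (1.19%), 48 of 1018 in vaccine 1 (4.72%) and 3 of 2039 in combination 2 (0.147%). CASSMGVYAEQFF was found in 5, 2 and 12 cells of the same libraries, and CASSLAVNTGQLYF in 1, 3 and 1. In the 5 other mice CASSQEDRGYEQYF was found in 0 cells, which allows a share of up to 0.121% (isotype 3) to 0.460% (isotype 2).

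A similar pair of chains was found in more cells of both combination mice than of any other mouse. The alpha chains had the form CAA, 2 residues, MGYKLTF, and the beta chains the form CAWS, 1 residue, RGV, 1 residue, TEVFF. The form was set after the sequences were seen, and its open positions lie where the chains of the combination mice differ. Its higher count in these mice thus follows at least in part from that choice. No splits of the mice were tried for it, so chance is not excluded. The pair was found in 67 cells of combination 1 (5.31%, in 22 clonotypes, with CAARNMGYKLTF). In combination 2 it was found in 98 cells (4.81%, in 1 clonotype, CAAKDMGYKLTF with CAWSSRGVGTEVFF). The pair was found in 1 cell each of isotype 2 and isotype 3 and in 0 cells of the others. Those cells had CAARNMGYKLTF with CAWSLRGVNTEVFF (isotype 2) or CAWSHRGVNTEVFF (isotype 3), forms also found in combination 1. The beta form alone was in 4 cells of isotype 2, 1 of isotype 3 and 1 of anti-PD1 1. In combination 1 and 2 it was in 76 and 106 cells. The 2 combination libraries had different forms of the chains. Carryover of this pair between libraries was not tested.

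Whether vaccination expanded T cells with shared receptors stays open, and chance is not excluded, since 3 of 56 splits of the mice had as many such sequences, the real one with 3 and the highest other with 5. By the mean share of cells in such sequences 1 of 56 splits, the real one, was as high, at 2.55% against 1.70% for the highest other, a value carried mostly by the 4.72% of vaccine 1. Molecules carried over between libraries are argued against as the whole cause between vaccine 1 and combination 1, where 9 of the 15 cells of combination 1 had a nucleotide form of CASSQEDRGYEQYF found in 0 cells of vaccine 1. For combination 2 carryover stays open, since only 1 of its 3 cells had a form of its own and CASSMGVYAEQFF had 1 form in all, although of the beta nucleotide sequences with at least 10 cells only 2 of 10 of vaccine 1 (2 cells) and 0 of 13 of combination 1 were found in it. Between other libraries such sequences were shared more often in places. Of combination 1, 5 of 13 were found in isotype 2 (7 cells), and of anti-PD1 1, 2 of 7 were found in combination 1 (10 cells). Of anti-PD1 2, 2 of 4 were found in vaccine 1 (3 cells). Of combination 2, 1 of 6 was found in combination 1 (5 cells) and in vaccine 1 (2 cells), and it is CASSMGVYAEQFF itself.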
